A study of Caulobacter vibrioides with 31 samples.

How the data were processed

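Total RNA was measured by stranded RNA sequencing in 31 libraries of Caulobacter crescentus, a freshwater bacterium, grown in defined M2-xylose medium. Per the labels, each culture was split, and 1 part received sucrose to a final 150 mM, a hyperosmotic stress. The libraries fall into sets that the labels mark MT (16 libraries, 5 h of further growth) and BS (15 libraries, 6 h). The MT set holds wild type and gsrN++, a strain that overexpresses the small RNA gene gsrN, with 4 untreated and 4 sucrose libraries each. The BS set holds wild type, with 4 and 4 libraries, and a strain deleted for sigT (ΔsigT), with 4 untreated and 3 sucrose libraries.

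The deposited tables list 4085 genes per library on the single chromosome. Per the file headers, total gene reads and unique gene reads are counts of reads per gene, and the values are whole numbers with a different total in each library. Per the file headers, a further column holds RPKM, reads scaled to gene length and library size; each library's RPKM was total gene reads divided by gene length and 1 constant, which was larger than the sum over the listed genes. The aligner, the counting tool, their versions and the strand setting are not given in the sources used here. The lane written in the labels was 6 for all MT libraries, 4 for BS wild type and 5 for ΔsigT, so that lane and strain cannot be separated in the BS set.

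Total gene reads were analysed. The 6 rRNA genes were left out before scaling. Genes were kept by edgeR's filterByExpr by group, which left 3924 genes in the MT set and 3931 in the BS set. Library sizes were scaled by TMM, and edgeR's quasi-likelihood F test was run in 1 model per set with 1 coefficient per group. The difference of the wild type responses between the sets was tested in a model of the 16 wild type libraries, as the BS response minus the MT response. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested in that comparison, and the adjusted p printed for single genes are from this edgeR test. Fold changes are log2, with a prior count of 2 in per-library log levels, and ± beside them is the standard error, obtained as the fold change divided by the square root of F. Levels are counts scaled to a common library size (CPM) after TMM scaling, as mean ± SD. There were 11 comparisons: sucrose against untreated in each strain of each set, each strain against wild type within each treatment, the interaction of strain and sucrose in each set, and the difference between the sets.

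A total of 24 gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. The lists were matched by gene symbol: general stress response core, oxidative stress defence, heat shock with chaperones and proteases, SOS and DNA repair, ribosomal proteins, translation factors and tRNA synthetases, RNA polymerase and sigma factors, ATP synthase and NADH dehydrogenase, terminal oxidases and cytochromes, TCA cycle, xylose use, sucrose use, TonB-dependent receptors, flagellum, chemotaxis, pilus and tight adherence, stalk and holdfast, S-layer and its export, cell cycle regulators and division, cell envelope and Tol-Pal, osmoprotection and compatible solutes, efflux pumps, iron homeostasis, and glyoxylate with storage and stationary phase. All 4085 genes were matched by start and end position to the reference annotation ASM2200v1, and 672 then had a symbol. That annotation carried no product text, so the sucrose use and TonB receptor lists had 0 members and others were short. Apart from rplS and rpsU, the ribosomal protein list came from neighbouring genes at CCNA_01305 to CCNA_01332. Apart from atpA and atpD, the ATP synthase and NADH dehydrogenase list came from nuo genes at CCNA_02015 to CCNA_02033. Counts and calls for these lists therefore describe mainly those clusters. The 18 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were also run. The only list calls that held with an estimated correlation were those of the general stress response core in ΔsigT against wild type, untreated and with sucrose. They held without the targeted gene too, a test chosen after the results were seen. Shorter lists are given as counts. All lists are reported for BS wild type, and mainly the called lists in the other comparisons. For lists reported, the number of members past the threshold is given over all genes tested and, where different, adjusted over the list alone.

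Genes were named by this rule. The targeted gene and the general stress response core are always named. Of the genes with adjusted p below 0.05, a mean of at least 10 CPM and every library of 1 group above every library of the other, the 10 largest rises and 10 largest falls qualified in the sucrose comparisons of wild type and in both strain comparisons with sucrose, and 5 and 5 in the others. Interactions needed the adjusted p and the mean alone. Up to 4 members with the smallest adjusted p were taken from each called list. Of genes without a symbol at most 2 per direction are printed in the results for these largest changes, and all of them where the differences of responses are listed at the end. The genes chvG, chvI, chvT and chvR, the znuL group and neighbours of CCNA_01194 are named outside this rule in places, and were chosen there after their values were seen.

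The library totals without rRNA ran from 14712000 to 23158000 reads (median 18714000), so that 3 reads over a group of 4 libraries correspond to about 0.0379 CPM in untreated ΔsigT. A fold against a group with 0 reads is given as a bound against 3 reads over the group, and a ratio over 1 to 3 reads with its 95% counting interval. Intervals and floors cover counting error only. With simulated counts of the same libraries, the model recovered 15 of 50 genes changed 1.25-fold, 46 of 50 changed 1.5-fold and 47 of 50 changed 2-fold in the MT set (wild type with sucrose), with 9 unchanged genes called, 5.42% of the calls. In the BS set (ΔsigT against wild type with sucrose) it recovered 9, 34 and 48 of 50, with 7 unchanged genes called, 4.73%. The simulated counts were independent between libraries, with 200 genes changed, as many up as down. They do not test the effect of shared cultures, or of scaling when many genes change.

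Alternatives tried were unique gene reads, upper-quartile and RLE factors, rRNA genes kept, DESeq2, limma on log2 of RPKM plus 1, a minimum of 10 CPM in 3 libraries, no filter beyond 1 read, the groups of a contrast alone, all 31 libraries in 1 model, a 2-fold minimum, a block for the library number (in ΔsigT also with the libraries matched by another number in the labels), and leaving out each library in turn. Unique gene reads, a fit of numbers 2 to 4 of every BS group and the list tests without the targeted gene were added after the data had been seen. Principal component 3 of the BS log levels held 10.6% of the variance. The number 1 libraries of every group scored −18.6 to −10.8 on it, and all others −1.93 to 11.8. This separation ran across strain and treatment, and its cause was not tested. A library number was taken to pair untreated and sucrose libraries of a strain where the log levels, centred by group, correlated above 0.1 in every pair. That held for MT wild type (0.161 to 0.268), BS wild type (0.135 to 0.473) and ΔsigT (0.276 to 0.672), not for gsrN++ (0.0585 to 0.286). The rule does not identify the pairs. In ΔsigT the matching by another number in the labels passed it too (0.23 to 0.672). In gsrN++ each untreated library correlated best with the sucrose library of its own number, while BS wild type untreated 2 did not. By the same rule the numbers paired wild type and ΔsigT untreated (0.137 to 0.77), not wild type and ΔsigT with sucrose (0.0409 to 0.539) or wild type and gsrN++. Overlaps were tested with Fisher's exact test, two-sided. No pair of libraries was a duplicate by a chi-square comparison of counts, whose lowest value per degree of freedom was 15.3. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.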

Results

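RNA levels of 4085 genes were measured in 31 libraries of Caulobacter crescentus in 8 groups. The MT set held 4 untreated and 4 sucrose libraries each of wild type and of gsrN++, a strain that overexpresses gsrN, the gene of a small RNA of the general stress response. The BS set held 4 untreated and 4 sucrose libraries of wild type, and 4 untreated and 3 sucrose libraries of ΔsigT, which lacks the gene of the sigma factor that directs that response. Reads without rRNA per library were 14712000 to 17479000 in MT wild type untreated, 17256000 to 21435000 with sucrose, 18491000 to 19933000 in gsrN++ untreated and 17061000 to 18976000 with sucrose. They were 15537000 to 21731000 in BS wild type untreated, 18354000 to 23158000 with sucrose, 17084000 to 23132000 in ΔsigT untreated and 19937000 to 21719000 with sucrose. The rRNA share was 0.0127% to 0.0484% of reads, 96.9% to 97.8% of reads were uniquely placed, and 61 to 89 genes per library had 0 reads. The gene with the most reads in each library was rsaA, which encodes the surface-layer protein, with 4.22% to 9.83%.

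The targeted genes set the strains apart. The gene sigT (position 3743953 to 3744558 on the chromosome) had 0 or 1 read in each ΔsigT library. Over the untreated groups it had 19504 reads in wild type and 2 in ΔsigT, a ratio of 9350 (95% counting interval 2590 to 77200). With sucrose it had 35983 reads in wild type and 0 in ΔsigT, at least 8460-fold lower against 3 reads over the group. The gene gsrN (3830130 to 3830241) was higher in gsrN++ than in wild type by 3.19 ± 0.32 on the log2 scale untreated (adjusted p = 2.05e-05, 6.67 ± 0.566 to 60.8 ± 23.3 CPM, n = 4 and 4) and by 3.15 ± 0.31 with sucrose (7.05e-07, 10.6 ± 0.991 to 93.8 ± 45.1 CPM). In ΔsigT, gsrN had 1 read untreated against 183 in wild type, a ratio of 175 (31.5 to 6930), and 3 with sucrose against 374, a ratio of 87.9 (30.1 to 426).

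**Figure D1:**
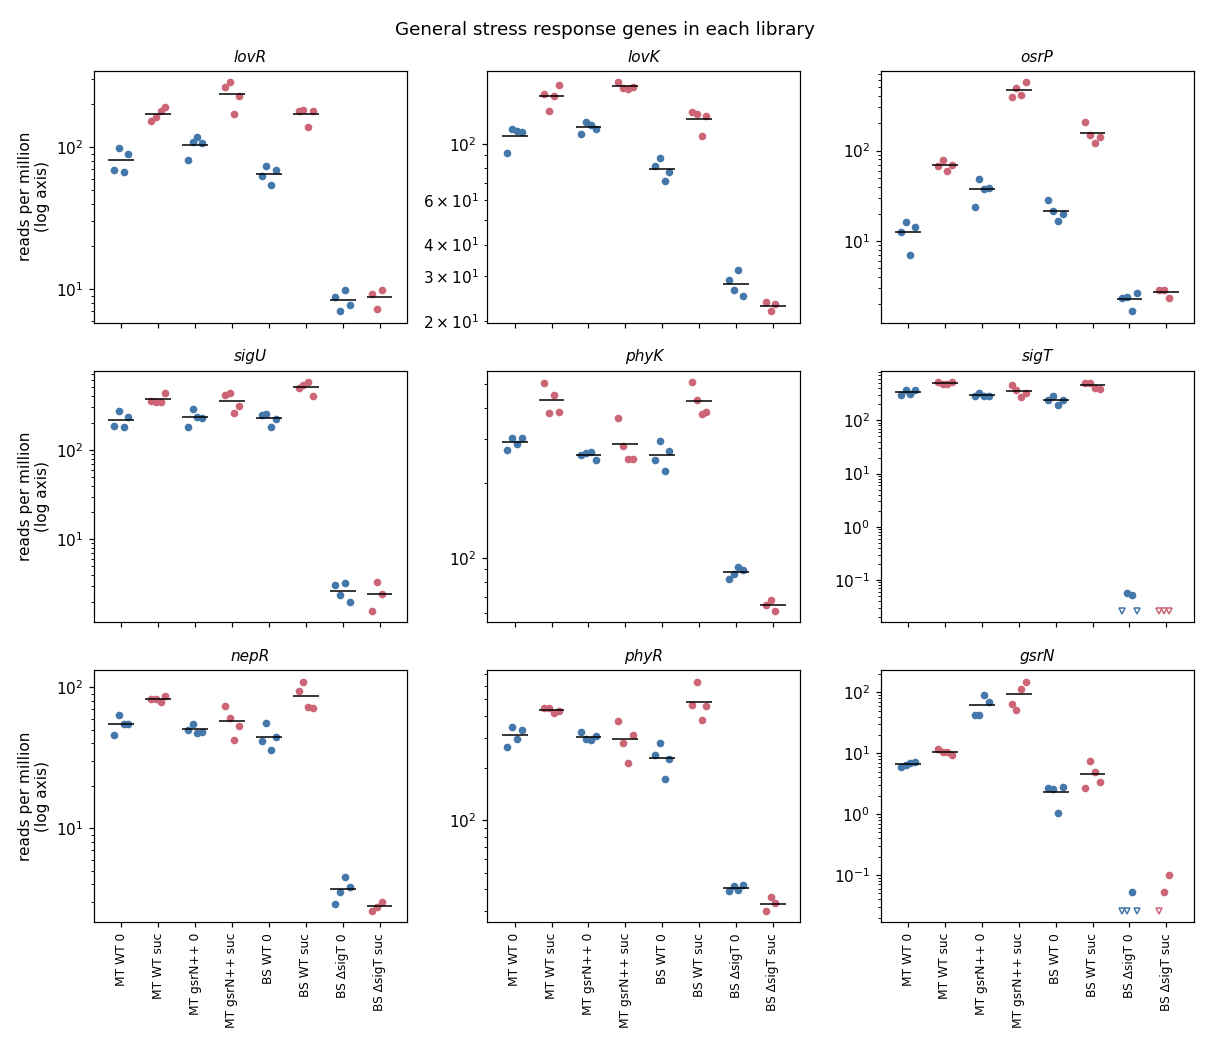
Levels of the 9 genes of the general stress response core in each of the 31 libraries, as CPM on a log axis, untreated in blue and sucrose in red, with a black line at the group mean where no library is at 0 and open triangles for 0 reads. The 4 BS wild type sucrose libraries have a mean of 155 for osrP and the 3 ΔsigT sucrose libraries a mean of 2.7.

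Wild type with and without sucrose in the BS set asks which transcripts change under hyperosmotic stress. All 9 measured genes of the general stress response core rose, by 0.65 to 2.84 on the log2 scale. The gene osrP rose from 21.6 ± 4.98 to 155 ± 37.2 CPM (2.84 ± 0.18, adjusted p = 1.54e-08, n = 4 and 4), and lovR, a response regulator, from 65 ± 8.42 to 170 ± 21 CPM (1.39 ± 0.13, 5.5e-07). The sigma factor gene sigU rose by 1.15 ± 0.16 (4.6e-05), sigT by 0.91 ± 0.14 (0.000117, 240 ± 37.2 to 452 ± 61.2 CPM), nepR, which encodes the anti-sigma factor that binds SigT, by 0.96 ± 0.15 (0.000126), and phyR, which encodes the response regulator that releases SigT from NepR, by 1.07 ± 0.15 (2.91e-05). The histidine kinase genes phyK and lovK rose by 0.71 ± 0.10 (3.55e-05) and 0.65 ± 0.09 (3.46e-05). The rise of gsrN by 1.04 ± 0.33 (0.0171) passed less firmly. With limma on RPKM its adjusted p was 0.0513, without wild type untreated 3 it was 0.0527 and without sucrose 2 it was 0.0831. As a list, the core rose against the other genes (camera adjusted p = 2.82e-06, adjusted p = 0.286 with an estimated correlation).

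Neighbouring protein-coding genes at 1311323 to 1317953 were among those with the largest rises in BS wild type, CCNA_01194 with 4.58 ± 0.67 (5.92e-05, 144 ± 20.5 to 3446.6 ± 788.9 CPM) and CCNA_01193 with 4.50 ± 0.46 (1.8e-06). Large falls were those of CCNA_03574, by −3.53 ± 0.14 (2.89e-10), and CCNA_03444, by −2.68 ± 0.15 (6.53e-09). Of 26 ribosomal protein genes, most of them from a cluster of neighbouring genes, 21 rose and 0 fell (camera 4.37e-05, adjusted p = 0.286 with an estimated correlation). The gene rplB was at 0.56 ± 0.08 and rpsH at 0.50 ± 0.11. On RPKM 7 of the 26 rose and 0 fell. Of 16 genes of ATP synthase and NADH dehydrogenase 5 rose and 0 fell, atpA by 0.65 ± 0.08 and atpD by 0.64 ± 0.10 (0.0129, adjusted p = 0.366 with an estimated correlation). On RPKM 3 of these 16 rose, 1 fell and their median was 0.01. All 5 TCA cycle genes rose, acnA (aconitase) by 0.40 ± 0.06, odhA by 0.36 ± 0.06 and sdhC by 0.46 ± 0.10 (0.00578, adjusted p = 0.286 with an estimated correlation).

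Stalk and holdfast, flagellum, chemotaxis, pilus and cell cycle genes fell as lists in BS wild type. Of 21 stalk and holdfast genes 18 fell and 0 rose, among them the stalk protein genes stpA (−1.09 ± 0.09) and stpX (−0.74 ± 0.10) and the holdfast gene hfsH (−0.69 ± 0.08) (camera 2.82e-06, adjusted p = 0.286 with an estimated correlation). Of 45 flagellum genes 16 fell and 2 rose (15 and 2 adjusted over the list alone), with the stator genes motA at −1.06 ± 0.15 and motB at −0.82 ± 0.11 (0.0055, adjusted p = 0.387 with an estimated correlation), against 24 lower and 0 higher on RPKM. Of 16 chemotaxis genes 10 fell and 0 rose, cheYIII by −0.58 ± 0.10 and cheAI by −0.41 ± 0.07 (0.00623, adjusted p = 0.286 with an estimated correlation). Of 14 pilus genes 8 fell and 0 rose, cpaK by −0.79 ± 0.09 and cpaL by −0.67 ± 0.10 (0.0237, adjusted p = 0.374 with an estimated correlation). Of 38 cell cycle and division genes 16 fell and 2 rose (0.0164, adjusted p = 0.286 with an estimated correlation), against 21 lower and 1 higher on RPKM. The response regulator genes divK (−0.90 ± 0.10) and pleD (−0.99 ± 0.12) and rcdA, which encodes a proteolysis adaptor (−0.48 ± 0.07), were among those that fell.

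Lists of metabolism were called in BS wild type as well. Of 6 xylose use genes 4 fell, xylX by −0.59 ± 0.08 and xylA by −0.39 ± 0.07 (camera 0.0376, adjusted p = 0.286 with an estimated correlation, 0.0606 with the library number as a block). Of 6 genes listed under osmoprotection 4 rose (0.0447, adjusted p = 0.286 with an estimated correlation, 0.055 with the block). They were putA (proline dehydrogenase, 0.58 ± 0.07), glnA (glutamine synthetase, 0.42 ± 0.08) and gltB (0.46 ± 0.11) with gltD, both of glutamate synthase, the last at 0.45 ± 0.13 (0.0105), with 0.0528 on RPKM and 0.0729 in numbers 2 to 4. Of 6 iron homeostasis genes 3 rose (6 adjusted over the list alone), exbB, which energises TonB-dependent uptake, by 0.42 ± 0.08 (0.0376, adjusted p = 0.286 with an estimated correlation), against 1 higher on RPKM. Lists without a call were heat shock (5 of 12 rose, 2 fell, camera 0.234), SOS and DNA repair (4 of 13 rose, 0.105) and S-layer (3 of 6 rose, 0.149), both with a median of opposite sign on RPKM, terminal oxidases (1 of 14 rose, 0 adjusted over the list alone, 0.868), cell envelope (1 of 18 rose, 6 fell, 0.105) and glyoxylate with storage (1 of 6 rose, 3 fell, 0.164). Of the shorter lists, 2 of 4 oxidative stress genes rose, the 1 translation gene rose, 2 of 4 RNA polymerase and sigma factor genes rose and 1 fell, and the 1 efflux gene fell by −0.41. Sucrose use and TonB-dependent receptors had 0 matched members.

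Of 3931 genes tested in BS wild type, 1894 were called, 929 higher (49%) and 965 lower, and 242 changed at least 2-fold. On RPKM the median of all genes shifted by −0.145 and 26% of the called genes were higher, so that rises are smaller and falls larger on that scale by about that shift.

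The same question in the MT set, after 5 h, gave rises past the threshold in 8 of the 9 core genes of wild type. The gene osrP rose by 2.45 ± 0.23 (1.62e-07, 12.6 ± 4.06 to 69 ± 7.69 CPM, n = 4 and 4), lovR by 1.09 ± 0.16 (2.17e-05), sigU by 0.76 ± 0.17 (0.00131), nepR by 0.60 ± 0.13 (0.000971), sigT by 0.56 ± 0.12 (0.000741, 338 ± 41.3 to 499 ± 26.9 CPM), phyK by 0.56 ± 0.11 (0.000356), lovK by 0.52 ± 0.08 (3.36e-05) and phyR by 0.48 ± 0.12 (0.0031). The value of gsrN was 0.67 ± 0.33 and did not pass (0.0995), with libraries at 5.95 to 7.24 CPM untreated and 9.45 to 11.9 with sucrose. Its standard error rests on a spread shared with the gsrN++ libraries. The SD of gsrN there was 23.3 CPM untreated and 45.1 with sucrose, against 0.566 and 0.991 in wild type. The missing call therefore does not show that gsrN was unchanged. The list rose against other genes (camera 0.000796, adjusted p = 0.277 with an estimated correlation). The largest rises of protein-coding genes were those of CCNA_01194, by 4.53 ± 0.21 (3.34e-11, 149 ± 7.71 to 3444.4 ± 398 CPM), and CCNA_02179, by 4.48 ± 0.13 (1.6e-13). The gene chvT, which encodes an outer membrane TonB-dependent receptor, rose by 2.54 ± 0.23 (1.37e-07, 2311.7 ± 768 to 13405 ± 2586.5 CPM). CCNA_03098 (−3.73 ± 0.19) and CCNA_01551 (−3.60 ± 0.17) fell. The zinc receptor gene znuL had −6.41 ± 1.58 (0.00271), with 1 of the 4 untreated libraries at 4810 CPM and the others at 16.1 to 266. Without that library the value was −2.80 (0.0316).

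Of 26 ribosomal protein genes, most of them from a cluster of neighbouring genes, 24 rose in MT wild type (camera 5.26e-08, adjusted p = 0.319 with an estimated correlation). The gene rpsH was at 0.78 ± 0.10 and rplN at 0.73 ± 0.10. All 5 TCA cycle genes rose, acnA by 0.45 ± 0.06 and odhA by 0.40 ± 0.06 (0.00487, adjusted p = 0.277 with an estimated correlation). Of 16 genes of ATP synthase and NADH dehydrogenase 9 rose (10 adjusted over the list alone), atpA by 0.67 ± 0.08 (0.0102, adjusted p = 0.352 with an estimated correlation), against 2 higher and 1 lower on RPKM. Of 21 stalk and holdfast genes 17 fell and 0 rose, stpA by −1.42 ± 0.10 (8.56e-09), stpB by −1.48 ± 0.15 and stpX by −1.11 ± 0.12 (8.4e-06, adjusted p = 0.277 with an estimated correlation). Of 45 flagellum genes 23 fell and 1 rose, the flagellin gene fljK by −1.08 ± 0.09 (3.7e-08) and motB by −0.54 ± 0.08 (0.00103, adjusted p = 0.352 with an estimated correlation), against 35 lower and 0 higher on RPKM. Of 38 cell cycle genes 17 fell and 3 rose, pleD by −0.87 ± 0.10, divK by −0.85 ± 0.09 and the polarity gene tipN by −0.43 ± 0.06, while mreB, which encodes the actin-like shape protein, rose by 0.45 ± 0.06 (0.0298, adjusted p = 0.38 with an estimated correlation). On RPKM 29 cell cycle genes fell and 1 rose.

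In MT wild type 2013 of 3924 genes were called, 942 higher (46.8%) and 1071 lower, and 281 changed at least 2-fold. On RPKM the median of all genes shifted by −0.159 and 23.9% of the called genes were higher. The chemotaxis list, with 9 of 16 lower and 1 higher (camera 0.0671), was called with the library number as a block (0.0499, adjusted p = 0.406 with an estimated correlation).

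The difference between the wild type responses of the sets, BS minus MT, was called in 30 of 3931 genes, 22 higher and 8 lower, with DESeq2 in 64. The gene with the smallest adjusted p was CCNA_02179, whose rise was smaller in the BS set by −1.82 ± 0.20 (0.000392), and CCNA_01551 had 1.90 ± 0.33 (0.0153). None of the 9 core genes differed by this test, with values from 0.12 ± 0.13 for lovK to 0.58 ± 0.21 for phyR (adjusted p = 0.317), but as a list the core was higher (camera 0.00507, adjusted p = 0.974 with an estimated correlation). The heat shock list was higher (0.0456) and ribosomal proteins were lower (0.00507), each with 0 members called and adjusted p = 0.974 with an estimated correlation. In both sets 660 genes rose, against 223 by independence, and 801 fell, against 264 (Fisher's exact p = 3.06e-293 for the rises). Across all genes the fold changes of the sets had a Pearson correlation of 0.816 and a Spearman correlation of 0.831, and genes are not independent replicates. Set, hours of growth and lane go together here, and the count ran from 6 genes without MT wild type sucrose 1 to 49 without BS wild type sucrose 1.

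The ΔsigT strain against wild type with sucrose asks which transcripts depend on the sigma factor under stress. Besides sigT, all 8 other core genes were lower in ΔsigT. The level of sigU was 502 ± 73 CPM in wild type and 2.47 ± 0.886 in ΔsigT (−7.65 ± 0.26, 6.93e-12, n = 4 and 3), that of osrP 155 ± 37.2 and 2.7 ± 0.324 (−5.84 ± 0.25, 8.81e-11), and that of nepR 86.7 ± 18.6 and 2.79 ± 0.191 (−4.95 ± 0.22, 1.39e-10). The values were −4.28 ± 0.16 for lovR, −3.87 ± 0.18 for phyR, −2.71 ± 0.12 for phyK and −2.45 ± 0.11 for lovK. The list, which includes the deleted sigT, was lower than other genes (camera 1.8e-15, adjusted p = 0.0339 with an estimated correlation). So were the 8 members without sigT (1.11e-13 and 0.031). The genes phyK, nepR and phyR lie directly beside sigT. For these, in each ΔsigT comparison, an effect of the deletion on neighbouring genes cannot be told apart from dependence on the sigma factor. The genes sigU, osrP, lovR, lovK and gsrN lie elsewhere. Among other genes CCNA_03668 (−9.04 ± 0.25, 1.03e-12, 384 ± 78.6 to 0.727 ± 0.196 CPM) and CCNA_01418 (−8.09 ± 0.22, 1.03e-12) were far lower. CCNA_01238 (4.92 ± 0.27, 1.59e-09, 24.5 ± 3.96 to 740 ± 260 CPM) and CCNA_00733 (3.88 ± 0.23, 3.14e-09) were higher.

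Cell envelope genes were higher in ΔsigT with sucrose, 13 of 18, with 3 lower (camera 1.86e-05, adjusted p = 0.538 with an estimated correlation). The genes of the sensor kinase ChvG and its response regulator ChvI were higher by 1.87 ± 0.10 (1.24e-09) and 1.70 ± 0.10 (3.45e-09, 506 ± 27 to 1650 ± 185 CPM), and tolA and tolR, of the complex that links outer and inner membrane, by 0.74 ± 0.08 and 0.78 ± 0.09. Another member, chvT, was lower by −3.12 ± 0.38. Stalk and holdfast genes were higher in 11 of 21 cases and lower in 1 (12 and 1 adjusted over the list alone), stpA by 0.68 ± 0.10 and hfaA, a holdfast anchor gene, by 0.43 ± 0.07 (0.000832, adjusted p = 0.567 with an estimated correlation), against 6 higher and 1 lower on RPKM. Of 45 flagellum genes 15 were higher and 2 lower, flbA by 0.59 ± 0.13 and fliL by 0.69 ± 0.17, while the flagellin gene fljO was at −1.03 ± 0.17 (0.016, adjusted p = 0.688 with an estimated correlation), and on RPKM 5 were higher and 2 lower. Of 6 xylose use genes 4 were lower, xylX by −0.40 ± 0.08 and xylB by −0.44 ± 0.11 (0.0464, adjusted p = 0.567 with an estimated correlation).

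In this comparison 1284 of 3931 genes were called, 610 higher (47.5%) and 674 lower, and 200 differed at least 2-fold. On RPKM 31% of the called genes were higher. Strain and sequencing lane cannot be told apart in the BS set.

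Untreated, ΔsigT already differed from wild type in the same list. All 9 core genes were lower, sigU by −6.38 ± 0.22 (6.75e-12, 226 ± 31.4 to 2.68 ± 0.596 CPM, n = 4 and 4), nepR by −3.59 ± 0.18, osrP by −3.25 ± 0.21, lovR by −2.95 ± 0.14, phyR by −2.50 ± 0.15, phyK by −1.56 ± 0.10 and lovK by −1.51 ± 0.09 (camera 1.75e-17, adjusted p = 0.0248 with an estimated correlation, and 3.6e-15 and 0.0246 without sigT). No other list was called. CCNA_00282 (−7.62 ± 0.25) and CCNA_01418 (−7.08 ± 0.19) were lower, and CCNA_03249 (2.10 ± 0.14) and CCNA_02755 (1.85 ± 0.15) were higher. In all, 944 genes were called, 470 higher (49.8%, against 34.6% on RPKM) and 474 lower, and 111 differed at least 2-fold. Between the treatments, 277 genes were higher in ΔsigT in both, against 72.9 by independence, and 347 lower in both, against 81.3 (Fisher's exact p = 1.35e-124 and 1.44e-194). Cultures were split between the treatments per the labels, so independence is not the value to expect without a strain effect.

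With sucrose inside ΔsigT, which shows the response that is left without the sigma factor, no core gene rose. The values were 0.25 ± 0.25 for osrP (0.459), 0.07 ± 0.15 for lovR (0.758, with −0.11 on RPKM), −0.12 ± 0.24 for sigU (0.734), −0.40 ± 0.22 for nepR (0.17) and −0.30 ± 0.16 for phyR (0.162). The gene phyK fell by −0.44 ± 0.11 (0.00495, n = 4 and 3), and lovK by −0.29 ± 0.10 (0.0341), a call lost without any 1 of ΔsigT untreated 1 (0.0701), untreated 3 (0.0992), sucrose 1 (0.0523), sucrose 2 (0.108) or sucrose 3 (0.0501) and in numbers 2 to 4 alone (0.11). Adjusted over the list alone 1 of the 9 fell. The reads of sigT (2 and 0) and gsrN (1 and 3) were too few for a fold. The cluster of CCNA_01191 (3.86 ± 0.15, 1.43e-10) and CCNA_01193 (3.80 ± 0.45, 1.18e-05) still rose, and CCNA_03574 (−3.90 ± 0.17) and CCNA_03444 (−3.60 ± 0.18) fell.

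Several groups moved in ΔsigT as lists. Of 6 xylose use genes 5 fell (6 adjusted over the list alone), xylX by −1.03 ± 0.09 (2.62e-07, 5630 ± 407 to 2755.6 ± 169 CPM) and xylB by −0.92 ± 0.11 (camera 0.000127, adjusted p = 0.263 with an estimated correlation). Of 16 chemotaxis genes 13 fell (14 adjusted over the list alone), cheU by −0.57 ± 0.09 and cheAI by −0.48 ± 0.08 (0.000127, adjusted p = 0.263 with an estimated correlation). Of 21 stalk and holdfast genes 14 fell and 1 rose (17 and 2 adjusted over the list alone), hfsH by −0.66 ± 0.09 and hfsK by −0.82 ± 0.14 (0.000311, adjusted p = 0.41 with an estimated correlation), against 17 lower and 0 higher on RPKM. Of 38 cell cycle genes 13 fell and 5 rose (17 and 6 adjusted over the list alone), the division gene ftsA by −0.62 ± 0.08 and ccrM, a DNA methyltransferase gene, by −0.81 ± 0.12, while ftsN rose by 0.49 ± 0.07 (0.0282, adjusted p = 0.41 with an estimated correlation). On RPKM 26 of them fell and 2 rose. Of 18 cell envelope genes 13 rose and 2 fell (14 and 3 adjusted over the list alone), chvI by 0.60 ± 0.10 and tolQ by 0.49 ± 0.07, while murD, of peptidoglycan synthesis, fell by −0.40 ± 0.07 (0.00138, adjusted p = 0.41 with an estimated correlation). On RPKM 8 rose and 3 fell. Of 26 ribosomal protein genes 9 rose, rplB by 0.44 ± 0.09 (0.000392, adjusted p = 0.41 with an estimated correlation), against 3 on RPKM. Of 6 S-layer genes 4 rose (5, with 1 that fell, adjusted over the list alone), rsaA by 0.60 ± 0.10 and rsaFa, of its exporter, by 0.66 ± 0.10 (0.0282, adjusted p = 0.263 with an estimated correlation), against 2 higher and 1 lower on RPKM.

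The ΔsigT sucrose comparison called 1558 of 3931 genes, 742 higher (47.6%) and 816 lower, and 199 changed at least 2-fold. On RPKM the median of all genes shifted by −0.174 and 17.2% of the called genes were higher. Of genes that rose, 472 were shared with BS wild type, against 175 by independence, and of those that fell 638, against 200 (Fisher's exact p = 3.28e-155 for the rises). Across genes the Pearson correlation of the strains' fold changes was 0.73, and genes are not independent replicates.

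**Figure D2:**
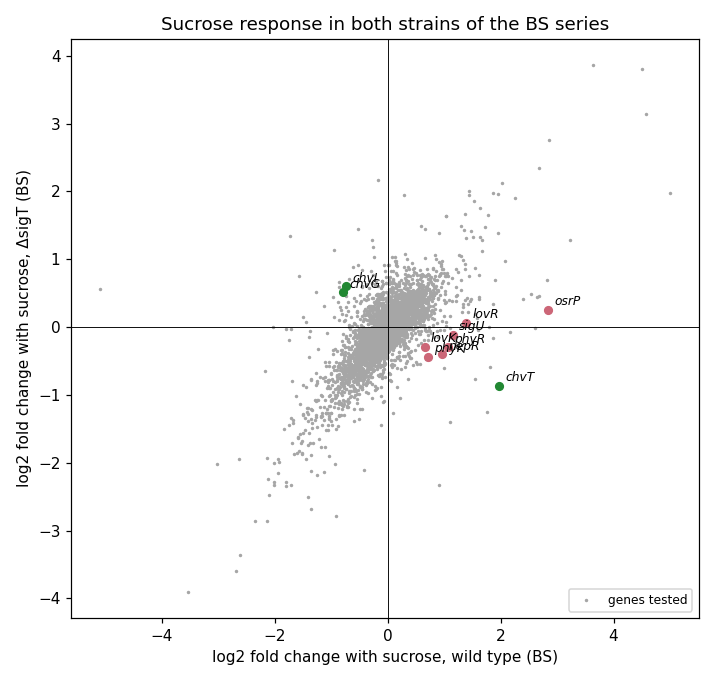
Log2 fold change with sucrose of each tested gene in BS wild type (x axis) and in ΔsigT (y axis), with the core genes other than sigT and gsrN in red and chvG, chvI and chvT in green. The gene osrP lies at 2.84 in wild type and 0.25 in ΔsigT, and chvI at −0.74 and 0.60.

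The interaction of the sigT deletion with sucrose tests which responses differ between the strains. The response was lower in ΔsigT for osrP (−2.59 ± 0.31, 0.000142), phyR (−1.37 ± 0.22, 0.00151), nepR (−1.37 ± 0.27, 0.00713), lovR (−1.32 ± 0.20, 0.000891), sigU (−1.27 ± 0.29, 0.0161), phyK (−1.15 ± 0.15, 0.000253) and lovK (−0.94 ± 0.14, 0.000676), 7 of 9 core genes (camera 1.48e-09, adjusted p = 0.0985 with an estimated correlation). The call of sigU was lost without ΔsigT sucrose 1 (0.0554) or sucrose 3 (0.0524), and in numbers 2 to 4 alone (0.139), as was that of nepR (0.0696). The response of the cell envelope list was higher in ΔsigT in 11 of 18 genes and lower in 1 (14 and 3 adjusted over the list alone), chvI by 1.34 ± 0.14 (6.35e-05), chvG by 1.30 ± 0.14 (6.35e-05) and tolQ by 0.58 ± 0.10 (0.00216), while chvT was lower by −2.84 ± 0.48 (0.00226) (1.48e-09, adjusted p = 0.0985 with an estimated correlation). CCNA_01238 (3.08 ± 0.33) and CCNA_00733 (2.33 ± 0.29) responded more in ΔsigT, and CCNA_03668 (−2.24 ± 0.34) and CCNA_00784 (−2.13 ± 0.32) less.

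Xylose use responded lower as a list in this interaction, with 3 of 6 genes called (6 adjusted over the list alone, camera 2.62e-05, adjusted p = 0.0985 with an estimated correlation). Flagellum (1 of 45 higher, 0 adjusted over the list alone, 0.00945, adjusted p = 0.622 with an estimated correlation), stalk and holdfast (1 of 21 higher, 0.00945, adjusted p = 0.609 with an estimated correlation) and pilus (0 of 14, 0.0135, adjusted p = 0.609 with an estimated correlation) responded higher as lists, with 0 members of each called on RPKM. In all, 237 of 3931 genes differed, 140 higher (59.1%) and 97 lower, and 59 by at least 2-fold. The count was 147 without ΔsigT sucrose 3, and smaller again without ΔsigT sucrose 1 and in numbers 2 to 4 alone.

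The gsrN++ strain against wild type with sucrose asks which transcripts change with more of the small RNA under stress. After gsrN itself the gene with the largest rise was osrP, from 69 ± 7.69 to 469 ± 81.3 CPM (2.76 ± 0.22, 1.24e-07, n = 4 and 4). Other core genes were lower, phyK by −0.59 ± 0.11 (0.000562), phyR by −0.56 ± 0.12 (0.0023), nepR by −0.53 ± 0.13 (0.0053) and sigT by −0.47 ± 0.12 (0.00669, 499 ± 26.9 to 360 ± 77.1 CPM). The values of lovK (0.13 ± 0.08, 0.24) and sigU (−0.06 ± 0.17, 0.851) did not pass. The rise of lovR by 0.47 ± 0.16 (0.0355) was lost on RPKM (0.0975) and without wild type sucrose 1 (0.105), 2 (0.0809) or 3 (0.0546) or gsrN++ sucrose 1 (0.089), 2 (0.121) or 4 (0.0569). With 3 higher and 4 lower, the core list had a median of −0.06, a mean of 0.48 and no call (camera direction up, 0.848, and down, 0.604, without gsrN).

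Neighbouring genes of myo-inositol uptake were higher in gsrN++ with sucrose, ibpA, whose product binds inositol, by 1.62 ± 0.12 (8.11e-08, 20 ± 0.422 to 61.7 ± 11.9 CPM) and the transporter genes iatA by 1.47 ± 0.11 (8.11e-08) and iatP by 1.36 ± 0.12 (3.07e-07), at 981935 to 985480. The quinol oxidase genes qoxB and qoxA were higher by 1.39 ± 0.20 (6.12e-05) and 1.34 ± 0.21 (0.000132), as were CCNA_01932 (1.41 ± 0.12) and CCNA_03694 (1.39 ± 0.11). The largest falls were those of CCNA_00600 (−2.76 ± 0.28, 1.05e-06) and its neighbour CCNA_03887 (−2.73 ± 0.26). Of 21 stalk and holdfast genes 7 were lower and 0 higher, stpX by −1.54 ± 0.12 (1.39e-07, 645 ± 52.5 to 221 ± 51.8 CPM), stpB by −1.37 ± 0.15, stpC by −1.34 ± 0.14 and stpA by −1.27 ± 0.10 (camera 0.0007, adjusted p = 0.7 with an estimated correlation). Of 16 chemotaxis genes 8 were lower and 0 higher, cheU by −0.38 ± 0.09 (0.00398, adjusted p = 0.7 with an estimated correlation).

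This comparison called 962 of 3924 genes, 411 higher (42.7%, against 25.8% on RPKM) and 551 lower, and 129 differed at least 2-fold.

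Untreated, gsrN++ differed from wild type in fewer genes, with osrP among the largest rises after gsrN, higher by 1.56 ± 0.22 (0.000422, 12.6 ± 4.06 to 37.2 ± 10.1 CPM, n = 4 and 4). The remaining core genes did not pass, with values from −0.18 ± 0.12 for sigT (0.348) to 0.35 ± 0.16 for lovR (0.163), −0.17 ± 0.11 for phyK, −0.12 ± 0.13 for nepR, −0.03 ± 0.12 for phyR, 0.09 ± 0.17 for sigU and 0.11 ± 0.08 for lovK. The gene iatA was higher by 0.76 ± 0.11 (0.000408), CCNA_02487 by 0.96 ± 0.11 and CCNA_02179 by 0.74 ± 0.12, and CCNA_03687 (−1.83 ± 0.19) and CCNA_01100 (−1.48 ± 0.12) were lower. The pilus list was lower with 1 of 14 genes called, cpaD at −0.34 ± 0.07 (0.0083), and the flagellum list with 1 of 45 (0 adjusted over the list alone), fliF at −0.34 ± 0.09 (0.0214), both at camera 0.0144 and adjusted p = 0.653 with an estimated correlation. On RPKM 1 flagellum gene was lower and 1 higher. The call of fliF was lost without wild type untreated 1 (0.056) or gsrN++ untreated 4 (0.058). In all, 374 of 3924 genes were called, 143 higher (38.2%) and 231 lower, and 21 differed at least 2-fold. The count was 190, with 29.5% higher, without gsrN++ untreated 4, 282, with 24.8% higher, without wild type untreated 4, and 574, with 42% higher, without wild type untreated 3. In both treatments 81 genes were higher, against 15 by independence, and 172 lower, against 32.4 (Fisher's exact p = 1.73e-44 and 1.08e-105). Here too the treatments share split cultures per the labels, so independence is not the value to expect without a strain effect.

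Within gsrN++, sucrose raised osrP from 37.2 ± 10.1 to 469 ± 81.3 CPM (3.65 ± 0.23, 7.95e-10, n = 4 and 4), lovR by 1.20 ± 0.16 (4.19e-06) and lovK by 0.54 ± 0.08 (1.31e-05). The rise of sigU by 0.61 ± 0.17 (0.00505) was lost on RPKM (0.0785). The values of gsrN (0.63 ± 0.28, 0.0592), sigT (0.27 ± 0.12, 0.0553), nepR (0.19 ± 0.13, 0.223), phyK (0.14 ± 0.11, 0.284) and phyR (−0.05 ± 0.12, 0.748) did not pass, and those of nepR and phyK were −0.07 and −0.11 on RPKM. As a list the core rose with 4 of 9 genes (camera 0.0354, adjusted p = 0.335 with an estimated correlation), against 3 higher and 1 lower on RPKM. CCNA_02179 (4.55 ± 0.13, 1.24e-13) and CCNA_03970 (4.23 ± 0.20) were among the largest rises. Among the largest falls was that of znuL, which encodes a TonB-dependent zinc receptor (−6.89 ± 1.61, 0.00133). It had 5540, 5990, 130 and 326 CPM in the 4 untreated libraries and 24.5, 30.8, 19.6 and 31.2 with sucrose. CCNA_01587 (−5.94 ± 1.64, 0.00467) was at 809, 705, 9.39 and 10.4 CPM untreated and 8.09, 5.54, 6.5 and 6.15 with sucrose, so that its fall rests on 2 untreated libraries.

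Of 26 ribosomal protein genes 24 rose in gsrN++, rplP by 0.72 ± 0.09 (camera 5.03e-06, adjusted p = 0.335 with an estimated correlation), and all 5 TCA cycle genes rose, odhA by 0.60 ± 0.06 and acnA by 0.64 ± 0.06 (0.00294, adjusted p = 0.335 with an estimated correlation). Of 16 genes of ATP synthase and NADH dehydrogenase 8 rose, atpA by 0.75 ± 0.08, atpD by 0.70 ± 0.11 (0.0362, adjusted p = 0.37 with an estimated correlation), but on RPKM 2 rose and 6 fell, with a median of −0.10. Of 6 iron homeostasis genes 5 rose, exbB by 0.53 ± 0.07 and hutA by 2.54 ± 0.44 (0.0407, adjusted p = 0.335 with an estimated correlation). On RPKM 2 of them rose, and sufC (0.27) and sufD (0.374) did not pass. Of 21 stalk and holdfast genes 18 fell, stpA by −2.33 ± 0.11 (4.04e-11, 221 ± 6.97 to 44 ± 8.69 CPM) and stpX by −2.13 ± 0.13 (5.08e-06, adjusted p = 0.335 with an estimated correlation). Of 45 flagellum genes 22 fell and 4 rose, motA by −1.63 ± 0.14 and fljK by −1.47 ± 0.09 (0.0362, adjusted p = 0.493 with an estimated correlation). On RPKM 32 fell and 0 rose. Of 16 chemotaxis genes 12 fell and 1 rose (14 and 1 adjusted over the list alone), cheD by −0.55 ± 0.08 and cheWI by −0.70 ± 0.10 (0.00698, adjusted p = 0.335 with an estimated correlation), against 15 lower and 0 higher on RPKM. Of 38 cell cycle genes 24 fell and 6 rose (24 and 7 adjusted over the list alone), staR, a regulator of stalk growth, by −2.22 ± 0.23 and pleD by −1.03 ± 0.10, while mreB rose by 0.76 ± 0.06 (0.0362, adjusted p = 0.391 with an estimated correlation), against 28 lower and 4 higher on RPKM.

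The gsrN++ sucrose comparison called 2344 of 3924 genes, 1101 higher (47%) and 1243 lower, and 455 changed at least 2-fold. On RPKM the median of all genes shifted by −0.22 and 22.2% of the called genes were higher. Of genes that rose 798 were shared with MT wild type, against 264 by independence, and of those that fell 944, against 339.

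The interaction of gsrN++ with sucrose tests which responses differ from those of MT wild type. The response was higher for osrP by 1.21 ± 0.30 (0.0289), a call lost without wild type untreated 2 (0.0687) or 4 (0.0639), wild type sucrose 1 (0.0596), 3 (0.0579) or 4 (0.0531), gsrN++ untreated 1 (0.0502) or gsrN++ sucrose 2 (0.0574) or 4 (0.0633). No other core gene passed: phyR had −0.53 ± 0.17 (0.0901), phyK −0.42 ± 0.15 (0.145), nepR −0.41 ± 0.18 (0.25), sigT −0.29 ± 0.17 (0.399), sigU −0.15 ± 0.24 (0.819), lovR 0.12 ± 0.22 (0.846), lovK 0.02 ± 0.11 (0.951, with −0.04 on RPKM) and gsrN −0.04 ± 0.42 (0.975). The stalk protein genes stpC (−1.19 ± 0.19, 0.00168), stpX (−1.02 ± 0.17, 0.00286) and stpA (−0.91 ± 0.14, 0.0018) responded with larger falls, and the list did so with 4 of 21 genes (5 adjusted over the list alone, camera 0.00764, adjusted p = 0.546 with an estimated correlation). CCNA_01931 (1.41 ± 0.18) and CCNA_00858 (1.21 ± 0.25) responded higher, and CCNA_00600 (−1.95 ± 0.37) and CCNA_03887 (−1.75 ± 0.34) lower.

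The heat shock list responded higher with 1 of 12 genes, which was ibpA (0.89 ± 0.17, 0.00637), listed by its symbol but lying beside the inositol transporter genes (camera 0.0153, adjusted p = 0.455 with an estimated correlation). The other called lists had 0 genes past the threshold: TCA cycle higher (0.021, adjusted p = 0.455 with an estimated correlation), chemotaxis lower (1 of 16 on RPKM, 0.0153, adjusted p = 0.455 with an estimated correlation) and S-layer higher (2 of 6 adjusted over the list alone, 0.0325, adjusted p = 0.363 with an estimated correlation). In all, 186 of 3924 genes differed, 34 higher (18.3%) and 152 lower, and 30 by at least 2-fold. DESeq2 called 286, with 30.4% higher, and the model with the library number as a block 306, with 29.1% higher, while on RPKM 231 were called, with 9.52% higher. The count was 111 without wild type sucrose 1, 117 without gsrN++ sucrose 3, 285 without wild type untreated 3 and 300 without gsrN++ sucrose 1.

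Overlaps between sets compare responses measured in separate libraries. Of genes that fell with sucrose in MT wild type, 298 were higher in ΔsigT than in BS wild type with sucrose, against 167 by independence (Fisher's exact p = 1.74e-35), and of genes that rose 211 were lower, against 162 (2.37e-06). The other pairs were 75 higher in both, against 146 (8.62e-15), and 189 lower in both, against 184 (0.669). Of genes that fell with sucrose in BS wild type 315 were lower in gsrN++ with sucrose (odds ratio 5.62, 2.18e-71), and of those that rose 180 were higher, against 97.4 by independence (1.59e-21), with 42 and 45 in opposite directions, against 130 and 101. Between the strain effects with sucrose, 150 genes were higher in ΔsigT and lower in gsrN++, against 85.4 (1.73e-14), and 88 lower in ΔsigT and higher in gsrN++, against 70.8 (0.0225), with 55 higher in both, against 64 (0.221), and 104 lower in both, against 94.6 (0.247).

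**Figure D3:**
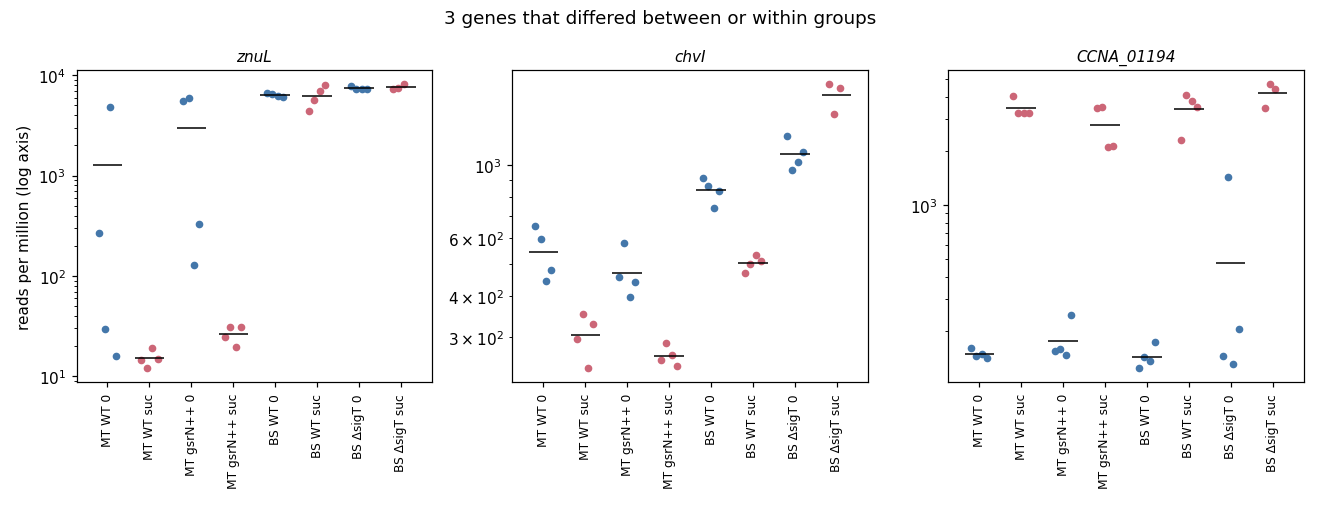
CPM of znuL, chvI and CCNA_01194 in each of the 31 libraries on a log axis, with a line at each group mean. The znuL level in MT wild type untreated is 4810 in library 3 and 16.1 to 266 in the others, and CCNA_01194 in untreated ΔsigT is 1430 in library 2 and 130 to 204 in the others.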

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

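The tests of mixing, of sucrose exposure and of single libraries for znuL, those of lane and scaling for chvG and chvI, the splits exchanging equally many libraries in both treatments and the comparison with splits parting as many pairs were chosen after the results were seen.

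The zinc receptor gene znuL and 3 other genes were uneven within untreated MT wild type and untreated gsrN++. In MT wild type untreated library 3, znuL was at 4810 CPM (the others 16.1, 29.9 and 266), CCNA_01587 at 628 (5.33, 6.37 and 12.3), CCNA_01588 at 1870 (19, 21.8 and 42.4) and CCNA_00700 at 494 (14.5, 22.8 and 62.6), and that library had the highest rRNA share of its group, 0.0484% against 0.0259% to 0.0293%. Reads from a BS library, where znuL was at 4430 to 8190 CPM, would have raised other genes too, but the highest median share over 14 BS libraries was 0.0243 against 0.582 or more needed, and the share by gsrN from gsrN++ libraries was 0.0124 against 0.799. An earlier form with all donors pooled gave a median share of 0.933 over 6 genes from gsrN++ untreated 2, past the 0.799 needed. However, 2 of the 6 genes neighbour CCNA_01587 and gsrN itself was not raised. A second form split the donors for libraries picked by level. From gsrN++ untreated 1 the genes were CCNA_00322, CCNA_01585, CCNA_01586, CCNA_02805 and gsrN, with a median share of 0.82. Genes beyond the 4 named above thus differed in wild type library 3 too. In the BS set the median change of the 4 genes with sucrose was −0.351 in wild type and −0.0485 in ΔsigT. In MT wild type it was −4.68, and −0.887 without untreated library 3. In gsrN++ it was −5.74, and stayed at −5.12 to −6.16 without any 1 untreated library. The BS libraries had high znuL with and without sucrose, while the MT sucrose libraries had 12.1 to 31.2 CPM. The BS values therefore cannot decide whether sucrose lowered these genes in the MT set. In gsrN++ untreated, znuL was at 5540, 5990, 130 and 326 CPM, CCNA_01587 at 809, 705, 9.39 and 10.4, CCNA_01588 at 1950, 1880, 27 and 31.5 and CCNA_00700 at 574, 518, 46 and 77.7, and the cause of these levels was not tested.

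CCNA_01194, which rose with sucrose in each strain, was at 1430 CPM in ΔsigT untreated library 2 against 130, 144 and 204. Carry-over of sucrose-treated cells or reads would have raised 30 other sucrose-induced genes by the same share, 0.314, but their median share was −0.0128 (quartiles −0.0993 and 0.0161).

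The genes chvG and chvI were higher in ΔsigT with sucrose, by 1.87 and 1.70. The lane follows the strain, but the difference between treatments within a strain does not. The smaller interaction of chvG and chvI lay 9.64 standard errors from 0, in genes already called in the interaction when this test was chosen. It covers only the interaction part, 1.30 and 1.34. Untreated, chvG and chvI were already higher in ΔsigT, by 0.57 (adjusted p = 0.000414) and 0.36 (0.0106). That part cannot be told apart from lane. Over 4 scalings the smaller of the 2 values stayed at 1.61 or more. Higher activity of the ChvG-ChvI system in ΔsigT than in wild type under sucrose is a candidate explanation. The small RNA gene chvR, which ChvI activates, was higher by 2.09 ± 0.41 (adjusted p = 0.00104). The gene chvT, which that small RNA represses, was lower by −3.12. The matching interaction of chvR was 1.10 (adjusted p = 0.312). Within ΔsigT, however, sucrose gave chvR 0.16 ± 0.38 (0.782) and chvT −0.87 ± 0.35 (0.0584). In BS wild type it gave chvR −0.94 ± 0.39 (0.0605) and chvT 1.97 ± 0.32 (0.000156). Untreated, chvR differed between the strains by 0.99 ± 0.37 (0.0629). The difference with sucrose therefore does not show that sucrose raised chvR in ΔsigT.

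Dixon's ratio was computed for 133 sets of 4 values, each set being 1 gene or the rRNA share in 1 group of libraries. Of these sets 16 had a deviating value, where 6.65 would by chance, 1 in 20. The znuL group and CCNA_01194 were included after their deviating libraries had been seen. The excess over 6.65 is therefore no evidence that deviating values were more frequent than by chance. Besides those given above, lovR was at 139.1 CPM in BS wild type sucrose 3 (179.8, 180.7 and 182.3), lovK at 92.05 in MT wild type untreated 1 (111.7, 112.7 and 114.1) and sigU at 437 in MT wild type sucrose 4 (341.7, 343.3 and 353). The level of sigT was 319.3 in MT gsrN++ untreated 2 (289, 291.4 and 291.5), that of gsrN 1.026 in BS wild type untreated 3 (2.575, 2.661 and 2.817) and 0.05232, 1 read, in ΔsigT untreated 3 (0, 0 and 0), and that of znuL 7790 in ΔsigT untreated 1 (7240, 7240 and 7260). CCNA_01194 was at 4040 in MT wild type sucrose 1 (3250, 3250 and 3270) and 244 in gsrN++ untreated 4 (147, 154 and 159), and chvG at 660 in MT wild type untreated 1 (485, 491 and 499).

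Responses that differed between strains numbered 186 for gsrN++, 237 for ΔsigT and 30 between the wild types of the sets. Among the genes named by rule or from called lists, the values for gsrN++ were osrP 1.21, CCNA_01931 1.41, CCNA_00858 1.21, CCNA_01932 1.21, CCNA_03619 0.95, ibpA 0.89, CCNA_00600 −1.95, CCNA_03887 −1.75, CCNA_00601 −1.64, CCNA_03283 −1.47, CCNA_00635 −1.36, stpC −1.19, stpX −1.02, stpA −0.91 and stpB −0.84, the last lost without MT wild type sucrose 1 (adjusted p = 0.0607), gsrN++ sucrose 3 (0.0559) or gsrN++ sucrose 4 (0.0515). For ΔsigT the genes named in that way were CCNA_01238 3.08, CCNA_00733 2.33, CCNA_03997 2.08, CCNA_01443 1.78, CCNA_02172 1.69, chvI 1.34, chvG 1.30, flbA 0.68, tolQ 0.58, stpA 0.53, chvT −2.84, osrP −2.59, CCNA_03669 −2.40 (adjusted p = 0.096 in numbers 2 to 4), CCNA_03668 −2.24, CCNA_00784 −2.13, nepR −1.37, phyR −1.37, lovR −1.32, sigU −1.27, phyK −1.15, lovK −0.94, xylD −0.46, xylA −0.44 and xylX −0.44. Calls of flbA, stpA, xylA, xylD and xylX were lost without single libraries. Between the sets the genes named in that way were CCNA_01551 1.90, CCNA_03997 1.61, CCNA_03098 1.55, CCNA_03568 1.28, CCNA_00220 1.27, CCNA_02179 −1.82, sapA −0.76, CCNA_03250 −0.70, CCNA_00451 −0.66 and CCNA_00856 −0.64.

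Other splits of the same libraries into groups of the same size called fewer genes than the real split in each of the 8 comparisons of 2 groups. Of 35 splits, 1 in each comparison, the real one, reached the count: 2013 genes in MT wild type with sucrose (highest other 34), 2344 in gsrN++ with sucrose (4), 374 and 962 for gsrN++ against wild type untreated and with sucrose (73 and 0), 1894 in BS wild type with sucrose (2), 1558 in ΔsigT with sucrose (734) and 944 and 1284 for ΔsigT against wild type untreated and with sucrose (0 and 648). The split with 734 moved ΔsigT untreated 1 to the sucrose libraries and that with 648 put BS wild type sucrose 3 with the ΔsigT libraries. For gsrN++ against wild type in both treatments, where the numbers do not pair the libraries by the rule used, this argues against chance. Among splits parting all 4 numbers there, the highest other was 13 untreated and 0 with sucrose. For ΔsigT against wild type with sucrose, the number 1 libraries correlated at 0.539, so that free exchange is doubtful. Splits parting all 3 numbers there were 8 with the real one, too few to decide, and the highest other called 329 genes. Where the numbers pair the libraries by that rule, the splits that part as many pairs were 8 with the real one. That is too few for a share under 5%. The highest other among them was 0 in MT wild type, BS wild type and ΔsigT with sucrose. It was also 0 in ΔsigT against wild type untreated. There, splits that part fewer pairs reached 34, 2, 734 and 0. For gsrN++ with sucrose, whose cultures were split per the labels without the pairs being given, the splits that part all 4 numbers were also 8, with the highest other at 0. For the interactions, 5 of 100 splits reached 186 for gsrN++ (highest other 700) and 5 of 100 reached 237 for ΔsigT (859). Between the sets 4 of 100 reached 30 (1780). With 100 random splits 4 and 5 cannot be told apart, so that this test does not exclude chance for any of them. Splits with several times the real count point to a structure of the samples, since a random split turns a strain or set difference into an interaction. Splits that exchanged equally many libraries in both treatments, drawn after this was seen, reached the counts in 1 of 100 each, with the highest other at 4, 1 and 0. Apart from the real one, every group in these splits mixed strains or sets, so that their difference widened the spread within groups. That lowers the calls with or without an interaction, so these splits do not exclude chance either.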

How the results depend on the processing

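Unique reads, the numbers 2 to 4 of the BS groups and the lists without the targeted gene were tests chosen after the data were seen. Of the values of named genes under the alternatives, 8661 kept direction and side of the threshold, 84 passed it, 214 no longer did and 29 changed sign. The causes of the changes below were not tested, apart from fewer libraries or a higher fold required. Counts at 2-fold or more were 281 (MT wild type), 455 (gsrN++), 21 and 129 (gsrN++ against wild type untreated and with sucrose), 30 (their interaction), 242 (BS wild type), 199 (ΔsigT), 111 and 200 (ΔsigT against wild type) and 59 (their interaction). The gsrN++ interaction called 286 genes with DESeq2 and 306 with the library number as a block, against 186, and the ΔsigT interaction 1.4e+02 in numbers 2 to 4 alone, against 237. The difference between sets was 16 with upper-quartile factors and 64 with DESeq2, against 30.

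Single libraries left out moved the gsrN++ effect untreated from 190 to 574, the gsrN++ interaction from 111 to 300 and the set difference from 6 (MT wild type sucrose 1) to 49 (BS wild type sucrose 1). Between those, the set difference was 7 without MT wild type sucrose 3, 8 without BS wild type untreated 2, untreated 3 or sucrose 3, 10 without MT wild type untreated 1, 12 without BS wild type sucrose 2, 13 without MT wild type untreated 4 or sucrose 2, 16 without MT wild type untreated 2 and 19 without BS wild type untreated 4. The ΔsigT interaction was 1.4e+02 without ΔsigT sucrose 1, 147 without sucrose 3 and 294 without BS wild type sucrose 3, and the gsrN++ interaction 117 without gsrN++ sucrose 3 and 285 without wild type untreated 3.

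Camera with an estimated correlation called 0 lists in the comparisons with sucrose of MT wild type, gsrN++, BS wild type and ΔsigT, in gsrN++ against wild type and in all interactions, and 1 in ΔsigT against wild type with sucrose. Without the targeted gene no list call changed by camera, with either correlation. With fry the counts were 16 (MT wild type, 7 by camera), 18 (gsrN++, 9), 0 and 5 (gsrN++ against wild type, 2 and 2), 2 (its interaction, 5), 11 (ΔsigT, 7), 6 and 9 (ΔsigT against wild type, 1 and 5) and 0 (between sets, 3).

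Overlaps at 2-fold, in the order higher in both, higher and lower, lower and higher, lower in both, were 1, 32, 36 and 16 for ΔsigT with sucrose response (1.82, 2.5, 4.16 and 5.7 expected), 4, 0, 2 and 24 for gsrN++ with sucrose response (0.611, 2.37, 0.99 and 3.85) and 0, 11, 6 and 2 for the strains (0.558, 2.17, 0.764 and 2.97). The 16 lower in both were more than expected (Fisher's exact p = 0.000139, odds ratio 3.29), unlike the 189 without a fold limit (0.669). For the pairs with fewer genes than expected without a fold limit (75, 42 and 45), the 1.82, 2.37 and 0.99 expected at 2-fold were too few to test a shortfall (odds ratios 0.537, 0 and 2.12).

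For gsrN++ the labels give split cultures, not which libraries share one. Each untreated library correlated best with the sucrose library of its own number, with 1 pair at 0.0585, and the block called 2473 genes, against 2344. Across strains the block called the stalk and holdfast list in gsrN++ untreated (0.0423, against 0.0612) and terminal oxidases in ΔsigT with sucrose (0.0127, against 0.631). By camera with an estimated correlation, without the block and the targeted gene, their adjusted p were 0.72 and 0.994.

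Values that changed sign on RPKM were phyK −0.11, nepR −0.072 and nuoC −0.012 in gsrN++, lovK −0.042 (gsrN++ interaction) and lovR −0.11 (ΔsigT). In numbers 2 to 4 sigU was 0.19 in ΔsigT, and with a block lovR was −0.0091. With 1 library left out, signs changed over these ranges: phyR −0.18 to 0.075 in gsrN++ with sucrose (without its sucrose 1 and 3), and −0.097 to 0.030 for gsrN++ against wild type untreated (without wild type 1 and 2). The gene sigU ran from −0.042 to 0.21 there (without gsrN++ 2 and wild type 2), from −0.17 to 0.064 with sucrose (without gsrN++ 2 and 3) and from −0.40 to 0.10 in ΔsigT (without sucrose 2 and 1). In the gsrN++ interaction lovR ran from −0.0011 to 0.25 (without wild type untreated 2 and gsrN++ sucrose 3), lovK from −0.037 to 0.083 (without wild type sucrose 2 and untreated 1) and gsrN from −0.35 to 0.21 (without gsrN++ sucrose 4 and untreated 3). In ΔsigT lovR was −0.052 without sucrose 3. The sign of gsrN in the ΔsigT interaction also changed (−0.55 on RPKM, −0.23 without ΔsigT sucrose 3, 2.2 without untreated 3), but with 1 and 3 reads in ΔsigT these values are not usable as folds.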
